A study of Mus musculus with 45 samples.

How the data were processed

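The series holds 45 samples of mouse heart, of which 6 RNA-seq libraries were analysed here. The other 39 are chromatin immunoprecipitation and input libraries, which were not analysed here. The 6 RNA-seq libraries fall into 5 groups by the sample titles. Adult heart has 2 libraries, and E12.5 heart, E12.5 heart labelled Gata4 KO, banding and sham have 1 each. Per the labels' protocols, 2 µg of pooled RNA went through poly(A) selection and random-hexamer reverse transcription. Nothing in the labels says that the 2 adult libraries came from separate animals or separate pools. A p-value therefore measures only the spread between these libraries, which may be technical.

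Per the submitters' processing notes, the tools named for the series are CASAVA 1.8.2, TopHat 1.4, HTSeq 0.5.3, BWA 0.5.9 and MACS 1.4, and the genome build is mm9. Which of these made the expression files is not given in the sources used here. Each deposited file lists 23284 gene symbols with 1 value each and no coordinates, so positions are not reported. The values deposited by the authors are on a log2 scale, log2(FPKM + 1), although the files are named for FPKM (fragments per kilobase of transcript, scaled to mapped reads). The scale was read from the values. After undoing log2 and subtracting 1, the low values of a gene stood in whole-number ratios between libraries, and they did not under a natural log, log10 or no transformation. The design had planned to take log2(FPKM + 1), so the values were used as deposited, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

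Whole reads could be recovered from those ratios for 99.99% of the 98043 values above 0, within 0.001 of a read. This gave 12619710 and 12357585 mapped reads for the adult libraries, 21056784 for E12.5, 17805109 for the E12.5 library labelled Gata4 KO, 14015985 for banding and 12086929 for sham. The reads on listed genes made up 81.7% and 82.2% of mapped reads in adult, 75.6% in E12.5, 76.6% in the library labelled Gata4 KO, 56.5% in banding and 53.9% in sham. FPKM divides by all mapped reads, so levels in banding and sham lie lower against the other libraries for most genes. The ribosomal RNA precursor Rn45s stood at 12.96 in banding and 12.94 in sham on the log2 scale, against 8.65 and 8.94 in adult, 7.56 in E12.5 and 6.21 in the library labelled Gata4 KO. Ratios of FPKM between single libraries carry exact 95% intervals from the recovered reads (conditional binomial). These intervals cover counting error only, since the reads carry no molecular identifiers. Counting does not separate near-identical copies, so values of genes with processed pseudogenes and of the globin family are uncertain.

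Adult was compared with E12.5 by limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, among 12658 genes with at least 1 FPKM in at least 1 of the 3 libraries. The spread came from the adult pair alone, with 1 residual degree of freedom and 1.535 prior degrees of freedom, and the lone E12.5 library was assumed to vary like the adult ones. Comparisons of 1 library with 1 library have no replicate check and no p-value. For these, and beside the test, a fixed rule of size counted genes that differed by at least 2-fold with at least 5 FPKM in the higher group. Between the 2 adult libraries the same rule counted 31 genes, 15 higher and 16 lower in replicate 1.

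A set of 30 gene lists was fixed before the data were examined, covering cardiac gene programmes, metabolism, matrix, signalling and markers of cell types or tissues that a heart sample could hold. Of their 653 entries, 617 matched a listed symbol, directly or by a synonym in the RefSeq gene table of GRCm38, which was used for names only. The list of mitochondrially encoded transcripts had no match. For each list and comparison, the median log2 difference was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Genes are not independent replicates, so such a percentile describes these libraries. Named genes followed a rule fixed at the same time. It took Gata4 first, then 10 cardiac sentinel genes, then the 10 largest differences in each direction by the rule of size, leaving out predicted genes, clones, small RNAs and pseudogenes, and up to 4 members of each list described, or up to 2 where no member passed. For the top genes of adult against E12.5 the limma test and the rule against each adult library were also required.

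The fit and the rule were tested on simulated reads with 200 changed genes, with noise of 7.6% beyond counting taken from the adult pair. Every simulated gene and library, E12.5 among them, was given this same noise. Recovery for genes that vary more, or with an E12.5 library that varies more than adult, was not tested. For adult versus E12.5, limma on 10890 simulated genes recovered 66 of 67 genes changed 2-fold, all 67 changed 3-fold and all 66 changed 8-fold, and called 24 unchanged genes. The rule of size, run on 19018 simulated genes, recovered 65 of 67 genes changed 3-fold in the simulation of the labelled Gata4 KO comparison and 66 of 67 in that of banding versus sham, and called 8 unchanged genes in each. In these simulations it recovered 22 of 67 genes changed exactly 2-fold, since such genes lie at its limit.

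There were 18 alternatives fixed before the data were examined. They covered the pseudocount, filters on low values, the minimum fold, scaling, the trend, the libraries in the fit and each adult library left out. After seeing the data, 4 more were added: limma with voom on the recovered reads, sham in place of adult, leaving out ribosomal protein genes and genes with a named processed pseudogene, and scaling to the reads on listed genes. Calculations used Python with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.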

Results

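Expression was measured by poly(A) RNA-seq in mouse heart at E12.5, in adult heart, and in hearts labelled banding and sham. Banding is an operation that narrows a great vessel and loads the heart, and the labels used here do not name the vessel. A further E12.5 library was labelled Gata4 KO. The study set out to relate the transcription factor Gata4 and histone marks to expression across development and heart disease. Adult had 2 libraries and the other 4 groups had 1 each, with 12086929 to 21056784 mapped reads per library. All levels below are log2(FPKM + 1), and levels of groups with 1 library have no error between replicates.

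Gata4 itself was measured in every library. It stood at 3.78 and 3.28 in the adult libraries, 5.93 in E12.5, 6.13 in the library labelled Gata4 KO, 2.38 in banding and 2.29 in sham. The library labelled Gata4 KO held 4159 Gata4 reads and the E12.5 library 4290, and the ratio of their FPKM was 1.15 with a 95% interval of 1.10 to 1.20 from counting. Gata4 was thus not lower in the library that carries the knockout label. The value spans the whole transcript, and the part that the floxed allele removes was not given in the labels, so the level does not show whether functional transcript remained. Directions drawn from this library rest on its label.

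**Figure D1:**
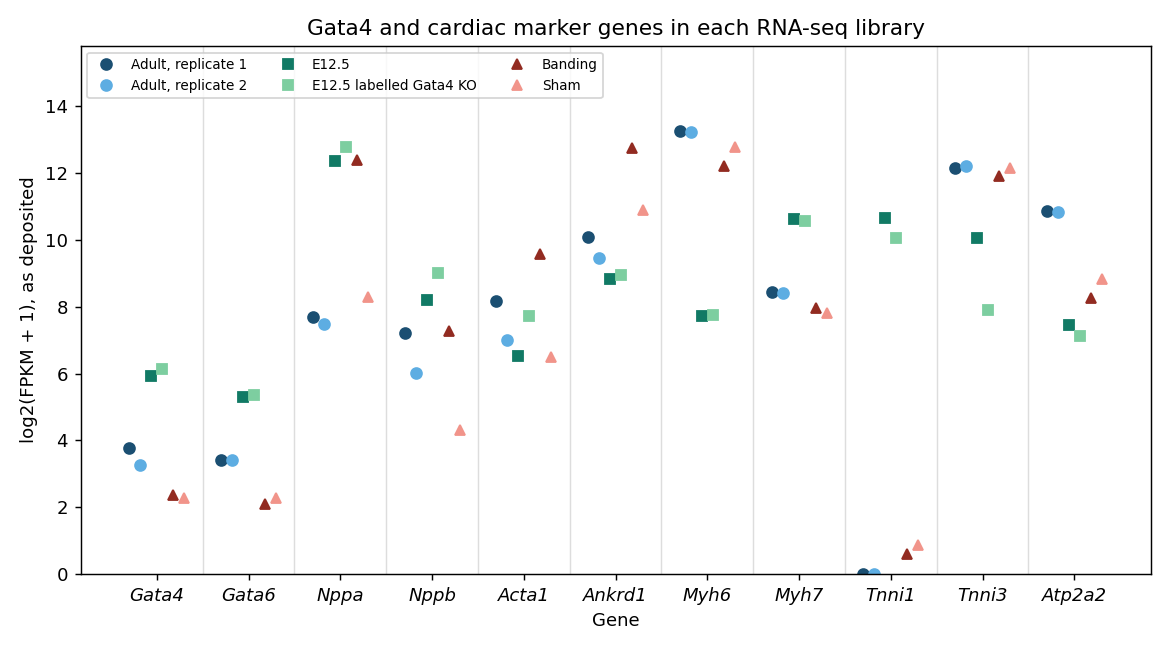
Level of Gata4, Gata6 and 9 cardiac genes in each of the 6 libraries, on the log2(FPKM + 1) scale, with 1 point per library. Gata4 lies at 5.93 in E12.5 and 6.13 in the library labelled Gata4 KO, and Nppa lies at 12.39 in banding against 8.28 in sham.

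The first comparison asked how the adult heart differs from the embryonic heart. Genes of adult muscle and of fatty acid use rose, and genes of the cell cycle, of fetal growth and of embryonic blood fell. Myh6, the adult myosin heavy chain of the mouse, rose from 7.72 in E12.5 to 13.24 ± 0.04 (SD, n = 2) in adult, a 45.9-fold difference. Tnni1, the slow skeletal troponin I of the fetal heart, stood at 10.66 in E12.5 and was listed at 0 in both adult libraries, while its adult counterpart Tnni3 rose by 2.14 (SE 0.10). Gata4 fell from 5.93 to 3.53 ± 0.36 (SD, n = 2), with a limma adjusted p = 0.0137, and the related factor Gata6 fell by 1.87 (SE 0.08, adjusted p = 0.00443). By limma, 2965 genes rose and 6123 fell among 12658 tested. By size, 1500 genes were higher and 3421 lower in adult, against 31 between the 2 adult libraries.

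Among the 20 sarcomere genes, 16 rose and 1 fell. Myom2, an M-band protein, rose by 8.05 (SE 0.06), Ckmt2, the sarcomeric mitochondrial creatine kinase, by 7.70 (SE 0.07) and the oxygen store Mb by 5.34 (SE 0.10), each with an adjusted p = 0.00398. Of the 18 genes of the fetal cardiac programme, 10 fell, 1 rose and 7 did not pass the test. Nppa, the atrial natriuretic peptide, fell from 12.37 to 7.59 ± 0.15 (SD, n = 2), Myh7 fell by 2.20 (SE 0.07), and the atrial light chains Myl7 and Myl4 fell by 7.34 (SE 0.75) and 5.31 (SE 0.35). The exception was Xirp2, which rose by 7.68 (SE 0.26). Nppb stood at 8.19 in E12.5 and 6.61 ± 0.86 (SD, n = 2) in adult and did not pass (adjusted p = 0.138), and neither did Acta1 (adjusted p = 0.239) or Ankrd1 (adjusted p = 0.116). In adult these 3 genes differed widely between the replicates.

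Of the 28 genes of fatty acid oxidation, 23 rose and 2 fell. The fatty acid transporter Cd36 rose by 6.39 (SE 0.12), the acyl-CoA synthetase Acsl1 by 4.61 (SE 0.06), the pyruvate dehydrogenase kinase Pdk4 by 4.44 (SE 0.08) and the uncoupling protein Ucp3 by 4.18 (SE 0.11). The size of these rises is that of the adult pair. In sham, 23 of 27 measured genes of this list lay lower than in adult by size, on the scale as deposited. The list was not compared between sham and E12.5. Glycolysis genes went both ways, with 8 that rose and 11 that fell of 21. The lactate carrier Slc16a3 fell by 5.80 (SE 0.12) and the glucose transporter Slc2a1 by 4.60 (SE 0.20). Of the enzymes, Tpi1 fell by 3.30 (SE 0.07) and Gapdh rose by 5.60 (SE 0.18), a value that is uncertain for the reasons given below. In calcium handling and ion channels, 22 of 35 genes rose and 8 fell. Among them Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose by 3.39 (SE 0.07), the potassium channel subunit Kcnip2 by 4.93 (SE 0.10) and the calcium-binding Hrc by 4.08 (SE 0.08), while the gap junction gene Gja5 fell by 4.81 (SE 0.20).

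All 35 cell cycle genes fell, with a median of -3.52, which lay at the 0 percentile of matched random lists. Rrm2, a subunit of ribonucleotide reductase, fell by 6.24 (SE 0.13), the cyclin Ccnb2 by 5.79 (SE 0.22) and the kinase Cdk1 by 5.22 (SE 0.12). All 21 imprinted and growth genes fell, among them H19 by 9.09 (SE 0.13), Mest by 7.56 (SE 0.18) and the growth factor Igf2 by 6.85 (SE 0.11). All 12 genes of the epicardium fell, including Krt19 by 4.49 (SE 0.14) and Tbx18 by 3.09 (SE 0.12). Of 32 matrix genes 21 fell and 7 rose, with Timp1 at -4.16, Fn1 at -4.06 and Vcan at -4.01. Of 25 cardiac transcription factors 17 fell and 3 rose. Nkx2-5 fell by 3.87 (SE 0.07) and Hey2 by 3.76 (SE 0.11), and Hand1 stood at 4.96 in E12.5 and was listed at 0 in adult. The embryonic globins Hbb-y, Hba-x and Hbb-bh1, markers of primitive red cells, stood at 13.71, 12.78 and 9.45 in E12.5 and were listed at 0 in adult, and in all 10 of 13 erythroid genes fell. Of 17 genes of sterol synthesis 15 fell. For each of these lists the counts adjusted over the list alone were the same as those adjusted over all genes.

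**Figure D2:**
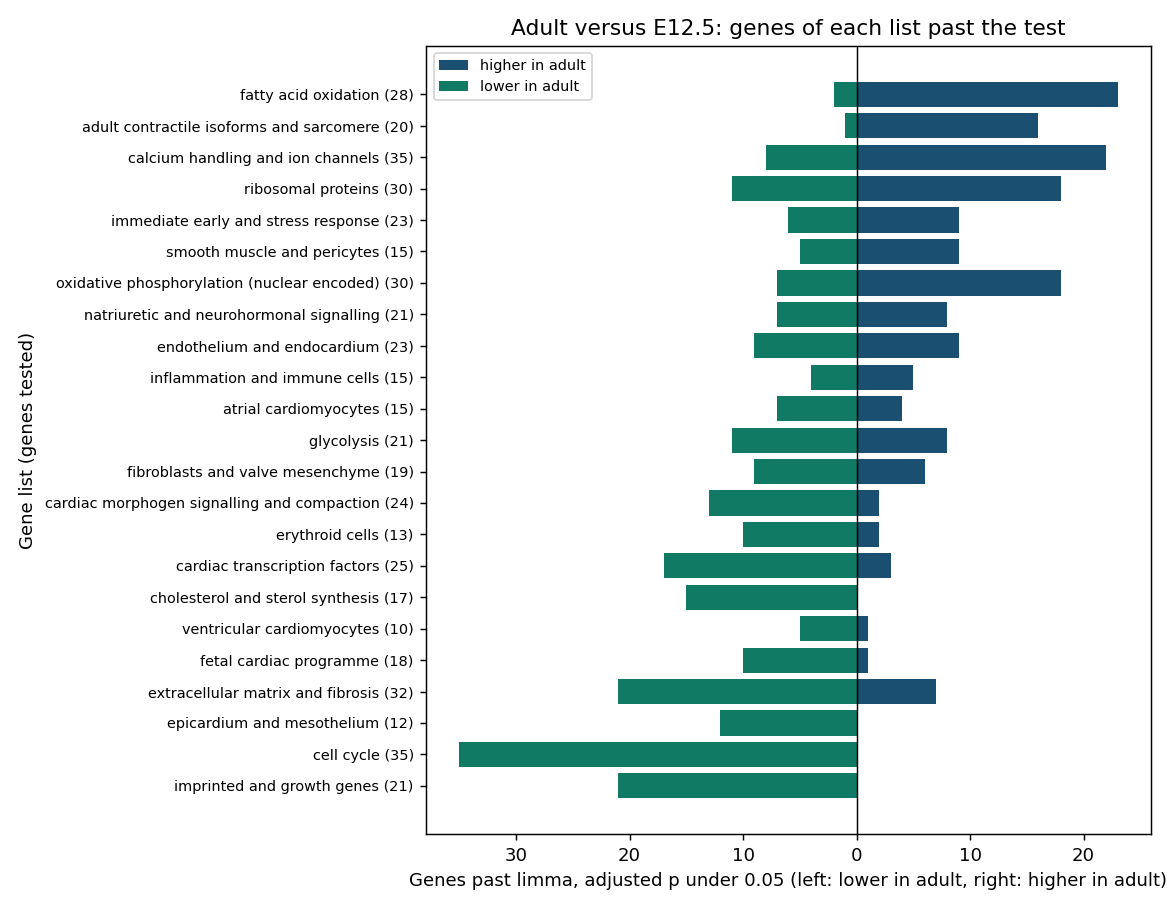
Number of genes past the limma test in adult versus E12.5 for each fixed list with at least 10 genes tested, with bars to the right for genes higher in adult and to the left for genes lower in adult, and the number of genes tested in parentheses. All 35 cell cycle genes lie to the left, and 23 of 28 fatty acid oxidation genes lie to the right.

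Genes of ribosomal proteins, which are made in fixed proportions, moved in opposite directions. Of 30 listed, 18 rose and 11 fell, also when adjusted over the list alone, with Rps6 among those that rose, at 5.30. Gapdh, a common reference gene, stood at 4.29 in E12.5 and 9.89 ± 0.22 (SD, n = 2) in adult. Cycs, Uqcrb and Cox6a1, which were among the largest differences (7.09, 6.29 and -7.45), also have near-identical copies and are uncertain. The balance of calls depended on scaling. The median over all tested genes was -0.51 as deposited and 0.02 after upper-quartile scaling, where 4316 genes rose and 4159 fell, and by size 2284 were higher and 2069 lower. The test held 1 E12.5 library. The other library from E12.5, labelled Gata4 KO, differed from it by 112 and 61 genes by size and held Gapdh at 4.27. A fault of that 1 library alone is therefore not the likely source of most differences. A technical effect shared by both E12.5 libraries would not show in this comparison and is not excluded by it.

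Banding was compared with sham to ask what the operation does to expression. The library of the banded heart held more transcript of cardiac stress genes and of matrix genes, and less of several metabolic genes. Nppa stood at 12.39 in banding and 8.28 in sham, a 17.4-fold ratio of FPKM (95% counting interval 16.8 to 18.0). Nppb, the B-type natriuretic peptide, stood at 7.27 against 4.31, the skeletal actin Acta1 at 9.59 against 6.48, and the stress-responsive cofactor Ankrd1 at 12.75 against 10.88. Myh7 differed little, at 7.97 against 7.81, as did Gata4 (2.38 against 2.29) and Gata6 (2.09 against 2.27). Myh6 was lower by 0.56 and Atp2a2 by 0.58 in banding, neither past the rule of size. By size 128 genes were higher and 51 lower in banding, against 31 between the adult libraries.

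All 34 measured matrix genes were higher in banding, 14 of them by size, with a median difference of 1.14 at the 100 percentile of matched lists. The largest were Timp1, an inhibitor of matrix proteases, at 3.69 against 0.55, the matricellular protein Postn at 5.13 against 2.02, the collagen Col8a1 at 5.15 against 2.86 and the growth factor Ctgf at 5.15 against 2.94. Of 19 fibroblast genes 18 were higher, 8 by size, among them Col1a1 (6.11 against 4.08), Mfap5 (3.99 against 2.14) and S100a4 (3.79 against 1.99). All 14 measured genes of the fetal programme were higher and 6 passed by size, including Xirp2 at 8.69 against 6.35. Tnni1 differed the other way but lay too low to enter that count, with 8 reads in banding and 11 in sham. In the stress response list 18 of 21 genes were higher, 4 by size, namely Serpina3n (2.67 against 0.78), the heat shock genes Hspb1 (6.66 against 5.01) and Hsp90aa1 (8.48 against 6.93), and Mt2 (5.18 against 3.95). Further genes higher by size were Rcan1, a target of calcineurin (4.69 against 2.64), Il11ra1 (6.17 against 3.63), Serpinb1c (5.87 against 2.00), Ankrd2 (2.97 against 0.10), Des (10.56 against 9.21) and Cryab (9.21 against 7.89). Immune cell genes had a median of 0.37 (99.99 percentile), with no member past the rule.

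Of 27 genes of fatty acid oxidation 22 were lower in banding, with a median of -0.36 at the 0 percentile, and 2 passed by size, Ucp3 (lower by 2.06) and the fatty acid transporter Slc27a1 (3.14 against 4.53). Calcium handling and ion channel genes had a median of -0.19 (0.01 percentile). Kcnip2 was lower at 2.82 against 4.32 and Casq1 higher at 5.32 against 3.89. The cardiac homeobox gene Hopx stood at 2.53 against 3.61, and Corin, the protease that activates natriuretic peptides, at 1.88 against 2.96. Pfkfb1 (0.87 against 2.73), Fblim1 (3.26 against 4.94), Ces1d (2.07 against 3.69), Penk (lower by 1.83), Phkg1 (1.52 against 3.13) and Inmt (0.98 against 2.59) were among the lowest. The lowest of all, Olfr39 and Retnla, held 5 and 7 reads in banding against 119 and 67 in sham. The endothelial list had a median of -0.12 (0.36 percentile) and no member past the rule.

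The number of genes lower in banding depended on scaling. It was 118 after rescaling without the 50 highest genes, beside 114 higher, and 87 after median-of-ratios scaling, beside 144 higher. With 1 library each, no difference between banding and sham has a replicate check.

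**Figure D3:**
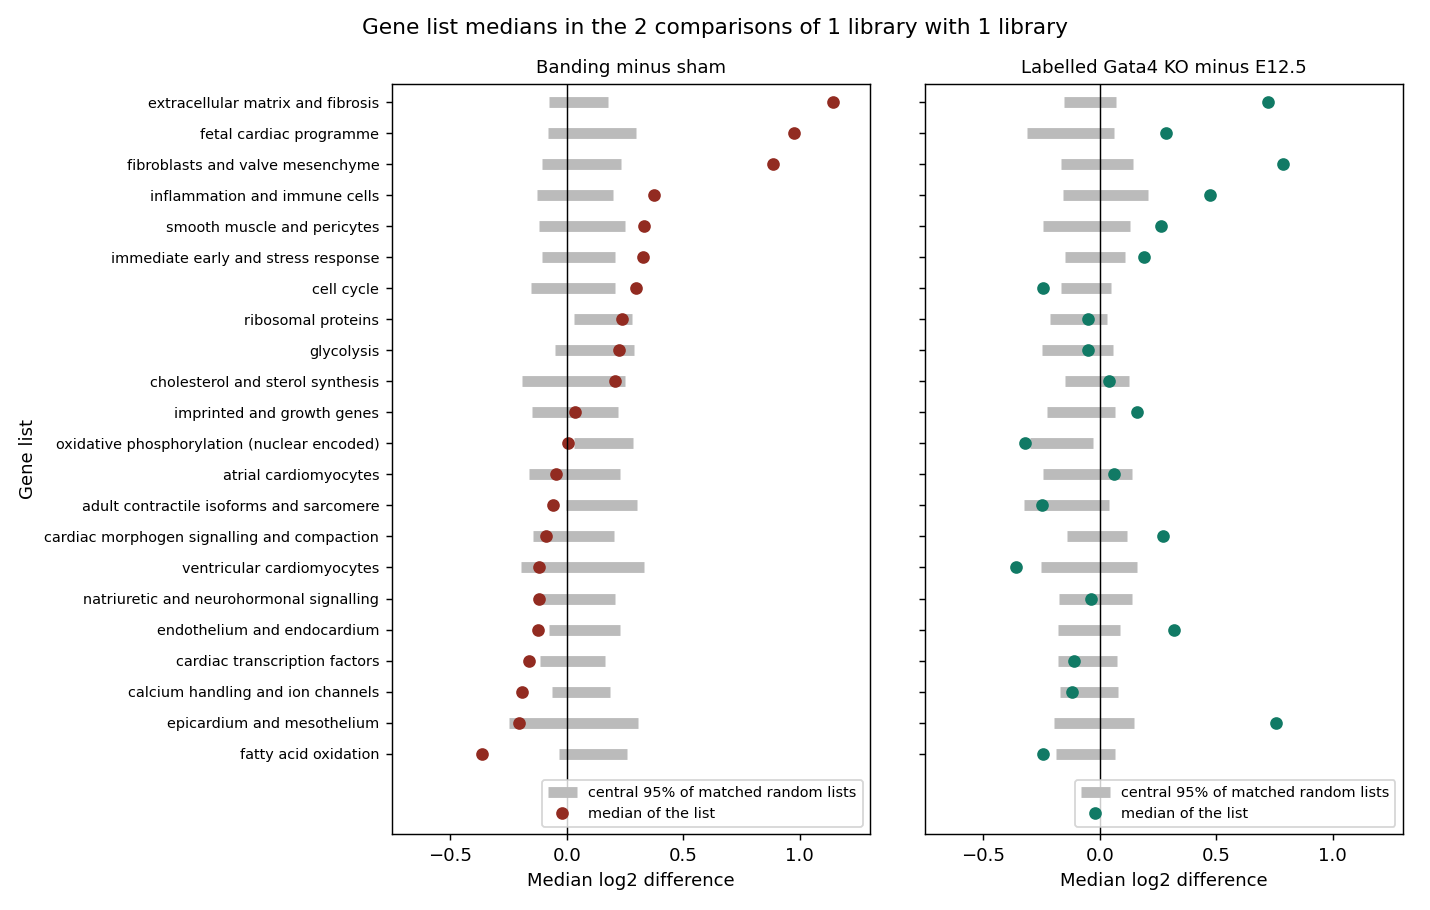
Median log2 difference of each fixed list with at least 7 measured genes in banding minus sham (left) and in the library labelled Gata4 KO minus E12.5 (right), as points, with grey bars for the central 95% of 10000 matched random lists. The matrix list lies at 1.14 on the left and 0.72 on the right, and the fatty acid oxidation list at -0.36 and -0.24.

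The library labelled Gata4 KO was compared with E12.5 to ask which genes depend on Gata4 in the embryonic heart. Genes of matrix, mesenchyme and primitive red cells stood higher in the labelled library, and a few muscle genes stood lower. Tnni3 was lower at 7.90 against 10.05, a 4.46-fold ratio of FPKM in favour of E12.5 (95% counting interval 4.30 to 4.62), and Mb at 6.11 against 7.88. Among the other cardiac sentinel genes, 4 lay close together: Myh6 stood at 7.76 against 7.72, Myh7 at 10.57 against 10.63, Ankrd1 at 8.95 against 8.84 and Gata6 at 5.36 against 5.29. Tnni1 was lower at 10.06 against 10.66 and Atp2a2 at 7.13 against 7.46, and Nppa was higher at 12.77 against 12.37, none of them past the rule of size. Nppb was higher at 9.02 against 8.19 without passing the rule, and Acta1 passed it at 7.71 against 6.54. By size 112 genes were higher and 61 lower in the labelled library. Without the 50 highest genes in the scaling, these were 121 and 40.

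Of 32 matrix genes 30 were higher in the labelled library, 8 by size, with a median of 0.72 at the 100 percentile. Postn stood at 5.34 against 3.83, Col3a1 at 6.50 against 5.13 and elastin, Eln, at 2.97 against 1.21, while Thbs4 was lower at 2.87 against 4.33. Of 18 fibroblast and valve mesenchyme genes 17 were higher (median 0.79), of 12 epicardial genes 11 (median 0.76) and of 22 endothelial genes 18 (median 0.32), and all 3 medians lay at the 100 percentile. Erythroid genes were higher in 13 of 14 cases, 5 by size. Hbb-y stood at 15.34 against 13.71, Hba-x at 14.33 against 12.78, Hbb-bh1 at 11.20 against 9.45 and the haem enzyme Alas2 at 7.92 against 6.57. The genes with the largest differences upward included Myot, a Z-disc protein (3.05 against 0.18), Sost (4.62 against 1.79), Igfbp7 (4.40 against 1.71), Sparcl1 (5.73 against 3.51), Spink4 (higher by 2.55), Adamtsl2 (3.21 against 1.09), Neil2 (2.86 against 0.74) and S100a9 (3.20 against 0.47). Edn1, encoding endothelin, stood at 3.96 against 2.32, Casq2, the cardiac calsequestrin, at 6.89 against 5.37, and the smooth muscle actin Acta2 at 9.83 against 8.56.

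Lower in the labelled library were also Tnni2 (3.90 against 5.77), Myh7b (2.53 against 4.09), Tcea3 (2.90 against 4.43), Sox3 (2.85 against 4.55), Ppp1r17 (1.39 against 3.58) and Fam40b (1.98 against 3.69). The ventricular list had a median of -0.36 (0.16 percentile), with 6 genes lower and 4 higher. By size 2 were lower, the potassium channel subunit Kcne1 at 2.40 against 3.75 and Hey2 at 4.92 against 5.93. Another 2 were higher, Gja3 at 3.32 against 1.82 and Slco3a1. Of 35 cell cycle genes 31 were lower (median -0.24, 0.05 percentile) with none past the rule. The growth regulator Mycn stood at 3.56 against 4.71. In oxidative phosphorylation 25 of 30 genes were lower (median -0.32, 1.41 percentile), with Uqcrfs1 at 6.93 against 8.20 and Cox5a at 9.31 against 10.46. Of the 5 measured sex-linked genes 4 were lower, with a median of -0.62 (0.02 percentile). Xist stood higher at 4.86 against 3.99 and Eif2s3y lower at 3.33 against 4.22. None of that list passed the rule of size, but a smaller shift in a pool need not pass it. Whether the share of female and male embryos differed is left open. With 1 library each, these differences have no replicate check.

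Sham was set beside adult as a background of hearts without banding. By size 2920 genes differed, of which 349 were higher and 2571 lower in sham. The balance followed the scale, since median-of-ratios scaling gave 1231 higher and 1183 lower. On the scale as deposited, 23 of 27 genes of fatty acid oxidation were lower in sham by size, with a median of -1.89 against -1.25 to -0.27 in matched lists. In the stress response list 21 of 22 were lower, 11 by size, with a median of -1.52 against -0.99 to -0.08. Rn45s lay at 12.94 in sham against 8.65 and 8.94 in adult. Atp2a2 lay at 8.84 in sham and 10.86 and 10.84 in adult, and the immediate early gene Fos at 0.35 against 4.87 and 4.78. In E12.5 Atp2a2 stood at 7.46 and Fos at 1.48. Sham thus lay above E12.5 for Atp2a2, by less than adult did, and below E12.5 for Fos. Myl7 and Sln, genes of atrial muscle, lay at 0.64 and 0 in sham, and in adult Myl7 at 4.65 and 3.27 and Sln at 3.18 and 1.67. Sham and adult therefore differed by more genes than banding and sham did.

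The last comparisons asked whether the banded heart shares genes with the embryonic heart. Over 2861 genes higher in E12.5 than in adult by size, the median banding minus sham difference was 0.09, against 0.01 to 0.04 in the central 95% of matched random lists, and 63.6% of these genes were higher in banding, against 54.4% of all measured genes. Over 1483 genes lower in E12.5 the median was -0.01, against 0.05 to 0.08. Genes higher in both banding and E12.5 numbered 40 where independent lists would share 25.7, and they included Nppa, Nppb, Timp1, Col1a1, Col3a1, Ccnd2, Sfrp1 and Hspb1. Genes higher in banding and lower in E12.5 numbered 34 where 25.4 would be shared, among them Acta1, Xirp2, Des, Cryab and Hsp90aa1. Genes lower in both numbered 25 where 9.03 would be shared, among them Ucp3, Slc27a1, Kcnip2, Corin and Ces1d. Across 13156 genes, which are not independent replicates, Spearman's rho between the 2 differences was 0.13 and Pearson's r 0.12. These comparisons share no library.

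Whether genes lower in the library labelled Gata4 KO stood apart in banding depended on scaling. Over 43 such genes the median was 0.03, at the 21.8 percentile of matched lists, in the values as deposited. It was -0.19 (0.20 percentile) after quantile normalization and -0.21 (0.78 percentile) when rescaled without the 50 highest genes. Genes higher in the labelled library stood apart in the values as deposited, with a median of 0.28 over 72 genes at the 100 percentile, and 10 genes were higher in both where 0.96 would be shared, namely Acta1, Bgn, Casq1, Col1a1, Col3a1, Mfap4, Mgp, Postn, S100a4 and S100a6. Across 13167 genes Spearman's rho between the 2 differences was 0.06 and Pearson's r 0.09. The 61 genes lower in the labelled library had a median E12.5 minus adult difference of 2.27, against 0.53 over all measured genes and -0.03 to 0.88 in the central 95% of matched lists, and 72.1% of them were higher in E12.5, against 64.1% of all. Of the 61, 39 were higher in E12.5 by size and 10 lower, where independent lists would share 26.2 and 6.63. The 39 included the small RNAs Snord49a, Snord49b, Snord52, Snord55, Snord57, Snord68, Snord82, Scarna17, Rnu11, Mir133a-2, Mir210 and Mir301b, and the predicted genes Gm8580 and Gm11968. The 10 included the ribosomal RNA precursor Rn45s. The 107 genes higher in the labelled library had a median of 0.98 (99.75 percentile), with 65.4% higher in E12.5. Of 76 with at least 5 FPKM in both comparisons, 38 were higher in E12.5 by size and 25 lower, where 32.7 and 8.26 would be shared. Both sides of these values use the E12.5 library. In 100 simulations with no effect the median for the lower genes was 1.17 (0.60 to 1.58), over lists of about 12 genes, far fewer than 61, and no such simulation was run for the higher genes. For the lower genes, part of the median of 2.27 and of the 39 may come from the shared library, which cannot be split. For the higher genes the shared library works the other way, since picking them favours a low E12.5 value. It could add to the 25, but not to the median of 0.98 or to the 38.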

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

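The alternatives scaled to reads on listed genes, with sham in place of adult, without pseudogene parents and with voom were chosen after seeing the data. Causes of the shifts below were not tested, beyond what a stricter or looser rule does by construction. No paired analysis was possible because only adult heart had more than 1 RNA-seq library. Both correlations, 0.13 and 0.06, kept their sign in every alternative run, as did the directions of named genes that passed the test or the rule of size. In adult versus E12.5, Ahsg lost its call with a pseudocount of 5 (adjusted p = 0.0585), and Ankrd1 gained 1 under upper-quartile scaling (adjusted p = 0.0444). Without an adult library limma has no residual degrees of freedom, so no test was run there.

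For adult versus E12.5, the limma count of genes that rose was 1878 with a minimum of 2-fold. With voom on recovered reads 3009 rose and 6938 fell, and without ribosomal protein genes and pseudogene parents 2846 and 5982. By size, higher and lower in adult were 871 and 1492 at 20 FPKM, 903 and 2280 at 3-fold, 2284 and 2069 with upper-quartile scaling, and 2153 lower with quantile normalization. With sham in place of adult 871 were higher and 4976 lower. Without an adult replicate the counts were 1466 to 1548 and 3404 to 3446.

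For the library labelled Gata4 KO, higher and lower were 47 and 31 with a pseudocount of 5, 51 and 32 at 20 FPKM, 378 and 297 at 1.5-fold, and 21 and 9 at 3-fold. Lower were 105 at 1 FPKM, 105 with no filter, and 40 when rescaled without the 50 highest genes. For banding, higher and lower were 62 and 17 with a pseudocount of 5, 200 and 107 at 1 FPKM and with no filter, 62 and 15 at 20 FPKM, 383 and 216 at 1.5-fold, and 37 and 12 at 3-fold. Lower in banding were 87 with median-of-ratios scaling, 81 with upper-quartile scaling, 94 with quantile normalization, 118 without the 50 highest genes, and 82 scaled to reads on listed genes. Sham versus adult gave 1696 with a pseudocount of 5, 1366 at 20 FPKM, 4488 at 1.5-fold and 1290 at 3-fold.

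The median of E12.5-higher genes in banding turned to -0.0020 when rescaled without the 50 highest genes, a scaling that moved the median of all genes in banding versus sham from 0.03 to -0.09. It still lay at the 100 percentile of matched lists. That of E12.5-lower genes turned to 0.0182 at 20 FPKM, still below its matched range of 0.07 to 0.12. The median of genes lower in the labelled library in banding, at 0.03, was -0.21 without the 50 highest genes, -0.19 with quantile normalization, -0.12 at 3-fold over 6 genes and -0.0114 with median-of-ratios scaling. The median of genes lower in the labelled library in E12.5 versus adult was 2.74 with a pseudocount of 0.1, 1.66 with 5, 1.49 at 1 FPKM and with no filter, 2.75 at 20 FPKM, 1.59 at 1.5-fold, 3.49 at 3-fold, 1.85 with upper-quartile scaling and 1.92 with quantile normalization. The oxidative phosphorylation list in banding versus sham, at 0.01, turned to -0.0387 with median-of-ratios scaling, -0.0087 with upper-quartile scaling, -0.20 with quantile normalization and -0.14 without the 50 highest genes. Depth limits low genes most, since 1 to 11 reads lie behind values such as Ankrd2 in sham and Tnni1 in both operated hearts.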

Other observations

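Other lists were measured as well, and not all of them stood apart. In adult versus E12.5, smooth muscle and pericyte genes went both ways, with the pericyte marker Rgs5 at 6.21 and the smooth muscle myosin Myh11 at 5.51, and the calponin Cnn1 at -4.31. Of 15 genes in that list 9 rose and 5 fell, the same as when adjusted over the list alone. The morphogen genes Bmp10 and Bmp7 fell by 5.75 (SE 0.17) and 5.49 (SE 0.13), and 13 of 24 genes of that list fell, also 13 when adjusted over the list alone. The immediate early genes Egr1 and Fos rose by 4.09 (SE 0.07) and 3.34 (SE 0.10), while Myc fell by 2.89 (SE 0.10). Fos lay lower in sham than in E12.5, so its rise held for the adult pair and not for sham. In that list 9 of 23 genes rose and 6 fell, the same as when adjusted over the list alone. Of 15 immune genes 5 rose and 4 fell, and 4 rose and 4 fell when adjusted over the list alone. Those of antigen presentation, Cd74 and H2-Ab1, rose by 3.48 (SE 0.34) and 2.95 (SE 0.22), and Ccl2 and Lyz1 fell by 2.03 (SE 0.10) and 1.53 (SE 0.12). Of the adipose list 3 genes could be measured and all 3 rose, also when adjusted over the list alone, with Plin5, a lipid droplet protein that heart muscle also makes, at 4.89. Lists for lung, liver or plasma, and thymus held 1 or 2 measured genes. By limma Ager of lung fell by 0.80 (adjusted p = 0.00544), Lck of thymus, at 1.11 in E12.5, was listed at 0 in adult (adjusted p = 0.00398), and Ahsg of liver rose by 0.78 (adjusted p = 0.0472), a call lost when adjusted over the list alone. None of them passed the rule of size. In banding versus sham, ribosomal protein genes were higher in 28 of 30 cases with a median of 0.24, at the 85.9 percentile and so within the range of matched lists. In the library labelled Gata4 KO, imprinted and growth genes had a median of 0.16 (99.89 percentile) and immune genes 0.48 (100 percentile).

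The test of a cardiomyocyte share and that of genes lower in banding were chosen after the results they bear on were seen, and so was the reason for setting the atrial test aside. Ribosomal protein genes differed between adult and E12.5 in opposite directions. Over 75 of them the SD of the difference was 2.66, within the range of matched lists in the same comparison (median 2.11, 94.1 percentile). It was 0.34 between the E12.5 libraries, 0.18 between banding and sham, 0.16 between the adult libraries and 0.82 between sham and adult. The spread was thus largest between stages, but sham and adult also differed by more than the adult pair. Stage and set of libraries cannot be told apart here, and a change with stage stays open, as untested. A candidate explanation is that reads shared with processed pseudogenes were assigned differently in the E12.5 libraries. The 60 genes with a named processed pseudogene had a median difference 2.61 above that of the 15 without (permutation p = 0.0312), and 2.61 (p = 0.0277) before Rpl3l and Rps27l, which are paralogues, were taken out after a first look. The predicted genes Gm6251 and Gm11968 stood at 10.11 and 9.40 in E12.5 and at or below 1.59 in adult, and Gapdh at 4.29 in E12.5 and 4.27 in the labelled library against 9.67 to 10.29 elsewhere.

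In the library labelled Gata4 KO, genes of several cell types other than muscle stood higher. A lower share of cardiomyocyte RNA would raise these by a like fold. The fibroblast median lay 0.47 above the endothelial one (0.79 over 18 genes against 0.32 over 22, permutation p = 0.00071 over genes). Genes are not independent replicates, so this p-value measures no spread between hearts. The scale also understates the change of low genes, and the test did not match the lists on expression. It therefore does not decide whether such a share is the only cause. Lists of muscle and of metabolism went both ways. The medians of the ventricular, fatty acid oxidation and oxidative phosphorylation lists were lower (-0.36, -0.24 and -0.32). The ventricular list was split, with 4 genes higher and 6 lower. The sarcomere list lay within the matched range (-0.25, 11.5 percentile). The fetal programme list, which also holds smooth muscle genes such as Tagln, was higher (0.28, 100 percentile). A change in mesenchymal, epicardial or red cells, a difference in dissection, the sex of the embryos and an effect of the labelled genotype stay open, as untested, and Gata4 itself was not lower.

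Several genes higher in banding also differed between the adult libraries. Nppb stood at 7.22 in replicate 1, 1.22 above replicate 2, Acta1 at 8.19 and 7.02, and Tnfrsf12a at 5.02 and 3.81. Nppb in adult replicate 1 was thus near the 7.27 of banding. The fixed lists went both ways between the replicates. The fetal programme and atrial lists were higher in replicate 1, with medians of 0.27 (100 percentile) and 0.19 (99.99 percentile). The matrix, fibroblast and immune lists, all higher in banding, were lower in replicate 1. Their medians were -0.21 (0.03 percentile), -0.30 (0 percentile) and -0.36 (0.01 percentile). The 118 measured genes higher in banding had a small median of 0.03 between the replicates (99.93 percentile of matched lists, 63 of 118 higher in replicate 1), which met the outcome written beforehand for a load response but restates the pattern and does not tell its cause. A load or stress response that varies between adult hearts would also lower the 49 genes lower in banding, and their median of -0.06 lay within the matched range (-0.09 to 0.03), which does not decide it. More atrial tissue in replicate 1, where Myl7, Myl4 and Sln were also higher, cannot be told apart from it: the median stayed at 0.029 without the atrial genes, which met the outcome written beforehand against it, but only 2 of the 118 genes were atrial.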
